A study of Mesocricetus auratus with 11 samples.

How the data were processed

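Reduced representation bisulfite libraries were made by the submitters from 100 ng of genomic DNA with a commercial kit, per the labels' protocols, for 4 MT2 wells given vehicle, 3 MT2 wells given 5aCdR and 4 primary fetal samples. The labels' protocol names 4 plates exposed to 5aCdR, and 3 libraries of that group were analysed here. Per the submitters' processing notes, bcl2fastq 2.20.0.42, Trim Galore 0.5.0, Bismark 0.22.1, Bowtie2, R 3.6.1 and methylKit 1.10.0 were used, without a statement of their settings. The genome build is not given in the sources used here, and scaffold names and 1-based positions are those of the files. In the deposited files, coverage is a count of reads over 1 strand of a CpG, and the levels of C and T are a percent of those reads, per the file headers. Each file listed positions with at least 10 reads only. Whether PCR duplicates were removed is not given in the sources used here.

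Methylated reads were recovered as coverage times the percent of C, rounded to a whole number, and the forward and reverse positions of a CpG were summed. Because each strand is listed only from 10 reads upward, a strand with fewer reads is missing from the sum. Both strands were listed at 32.1% of CpGs, each in at least 1 library and not necessarily the same one. The total of reads over CpGs per library was 17834610 to 46148127. Levels per library, other than mitochondrial ones, were means over CpGs with at least 10 reads in all 11 libraries, and groups were compared with an exact two-sided permutation test of the difference in means, which cannot go below p = 0.0286 for 4 against 3 or 4 against 4 libraries. Methylation levels have counting error that depends on the number of molecules, which is not known, so no interval from read counts is given.

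Single CpGs and non-overlapping tiles of 1000 bp with at least 3 CpGs were tested with a quasi-binomial logistic model on methylated and unmethylated reads, with 1 coefficient for the group. Units needed at least 10 reads per CpG in every library of the 2 groups compared. The Pearson dispersion per unit was moderated across units by the empirical Bayes method of limma and not allowed below 1. The prior was fitted on units with at least 10 methylated and 10 unmethylated reads. The F test on the deviance was adjusted by Benjamini-Hochberg over all units tested, and an adjusted p below 0.05 was a call. Windows of 100 kb with at least 10 CpGs, added after the data were examined, were tested in the same way. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16 were used.

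The tests were tried on simulated data with the real depths, in which reads were copies of fewer molecules and 200 units of intermediate level were changed. All units were drawn at the prior dispersion that the test had fitted. Recovery and false calls may therefore differ in the real data, as at tiles near full methylation. For 5aCdR against vehicle, 55% of 100 tiles changed by 30 points and 95% of 100 tiles changed by 50 points were recovered. Beside these recovered tiles there were 12 false calls among 18639 tiles. For MT2 against primary cells, 68% and 100% were recovered, with 7 false calls among 10178 tiles. Single CpGs had less power: of those changed by 50 points, 9% were recovered among 155920 in the first comparison and 28% among 91277 in the second.

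The design, the tests and most alternatives were chosen before the data were examined. The alternatives were a minimum of 20 reads, pooled reads, CpGs of each library on its own, separate strands, no dispersion, dispersion from all 3 groups, an upper limit on coverage, smaller tiles, at least 5 CpGs per tile, edgeR's quasi-likelihood test with a coefficient per library, limma on the mean over CpGs of log2((methylated reads + 1)/(unmethylated reads + 1)), a replicate block and each library left out in turn. The block fit took its prior from the fit without the block, since with its own prior too many unchanged CpGs and tiles of simulated data had a p below 0.05; this was changed after its first counts on the real data had been seen. edgeR was run first without and then with its default dispersion trend, and the latter is given. The windows, the density classes, the read shares, the checks of neighbouring CpGs and adjacent windows, and the split of the primary libraries were added after the data were examined. Regions named in the text were fixed as the 10 tiles with the largest fall and the 10 with the largest rise among tiles with an adjusted p below 0.05, a difference of at least 25 percentage points and no overlap between the libraries of the groups. If fewer met this, those that did were taken. The report gives some of the 10 in full and the range of the rest. The 3 largest windows each way among called windows without overlap are named in addition, a rule added later.

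A gene table of another assembly was at hand and its coordinates do not belong to these scaffolds. Promoters, gene lists and genomic context, which had been planned, were therefore not analysed here. CpGs were grouped instead by the number of CpGs, among the 2010882 covered in any library, within 250 bp on each side, a choice made after the data were examined. The planned minimum of 5 reads was not run because the files start at 10. Read shares of scaffolds and of 500-kb windows, used in the closing observations, were log2 shares of the summed coverage tested with limma over the 3 groups, with calls at an adjusted p below 0.05 and a log2 difference above 0.3 in size. Scaffolds needed at least 2000 CpGs and windows at least 300. No 2 libraries were alike enough to be 1 library deposited under 2 names: between any 2 libraries of a group the mean chi-square per CpG was at least 15.4 for 1 degree of freedom.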

Results

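DNA methylation was measured by reduced representation bisulfite sequencing, in which DNA is cut at a CpG-containing motif and the ends of the fragments are read after bisulfite treatment, in cells of the Syrian hamster (Mesocricetus auratus). Of the 11 libraries, 4 came from primary fetal cells, each from another female fetus at gestation day 13.5, a mixture of cells of ectodermal and mesodermal origin after fewer than 3 days and 1 passage in culture. The other 7 came from MT2, a female cell line that grew out of a colony morphologically transformed by benzo[a]pyrene (5 µg/mL), passed senescence and was at about passage 28. Of the MT2 libraries, 4 were from wells given the vehicle (0.05% DMSO) and 3 from wells given 5 µM 5-aza-2'-deoxycytidine (5aCdR), an inhibitor of DNA methyltransferases, for 48 h. The MT2 wells were seeded from 1 frozen stock, so their p-values measure the spread between wells and not between independently derived lines. The deposited files listed between 17834610 and 37595680 reads over CpG positions per vehicle library. They listed 36110136 to 46148127 per 5aCdR library and 19331056 to 37417483 per primary library. A library covered between 651397 and 1175553 CpGs with at least 10 reads on a strand, at a median of 20 to 27 reads per CpG. Over the 11 libraries 2010882 CpGs were covered at least once, and 81297 of them (4.04%) had at least 10 reads in every library. Levels per library refer to these common CpGs, except those of the mitochondrial sequence. Mitochondrial levels pool the reads of the 10 to 29 mitochondrial CpGs listed in each library, of which 8 were common to all 11. Copies of 1 molecule count as separate reads, so a read count can overstate the number of molecules behind a level. Reads of a library, tile or window are sums over its CpGs, so a read over several CpGs counts once at each. The genome build is not given in the sources used here, and regions are named by the scaffolds and 1-based positions of the files.

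The first comparison asked how 5aCdR changed methylation in MT2 cells. Methylation was lower after 5aCdR in each class of CpG density and of starting level, by the most percentage points at sparse CpGs and at CpGs of high starting level, and nearly all regions that passed the test had lost methylation. Mean CpG methylation was 33.2% ± 0.209 (SD, n = 3) after 5aCdR and 38.1% ± 0.0700 (SD, n = 4) with vehicle. It fell by 4.93 percentage points, a relative change of -12.9%. Each 5aCdR library, between 33.1% and 33.4%, lay below each vehicle library, between 38.0% and 38.2%. The exact two-sided permutation test gave p = 0.0286, the smallest value that the 35 splits of 3 against 4 libraries allow. CpGs of the mitochondrial sequence were called methylated in 2.44% ± 0.167 (SD, n = 3) of reads after 5aCdR and in 3.08% ± 0.455 (SD, n = 4) with vehicle (exact permutation test, p = 0.0857).

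**Figure D1:**
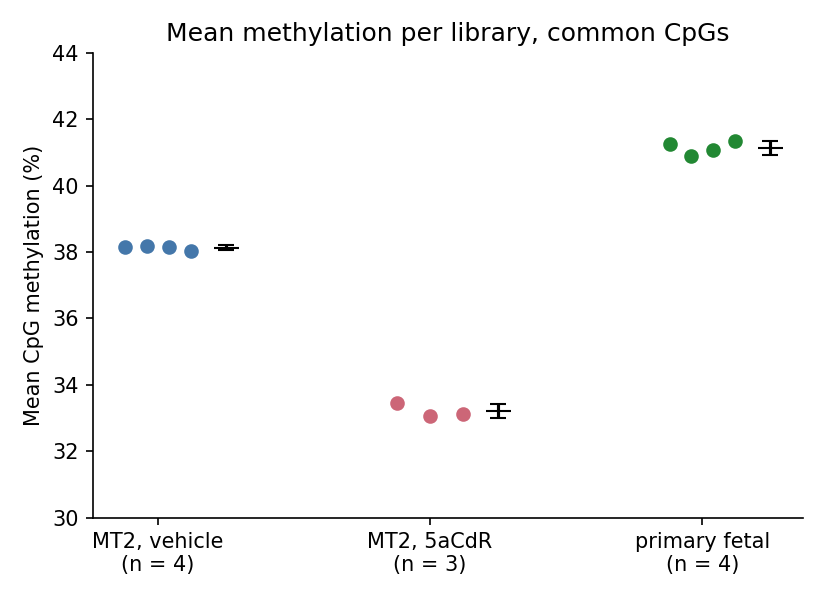
Mean CpG methylation (percent, y axis, drawn from 30 to 44) of each library over the 81297 CpGs with at least 10 reads in all 11 libraries. Each point is 1 library and the black marks are the group mean and SD. The 3 groups did not overlap, with 5aCdR at 33.1% to 33.4%, vehicle at 38.0% to 38.2% and primary cells at 40.9% to 41.4%.

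In the 5 classes of CpG density the relative changes lay between -15.3% and -12.7%. Density counts CpGs within 250 bp on each side that were covered in any library, the CpG itself included. CpGs of the genome without coverage are left out. The 24402 CpGs in sparse surroundings had 1 to 4 covered CpGs nearby. Their level was 46.9% ± 0.281 (SD, n = 3) after 5aCdR and 53.8% ± 0.0483 (SD, n = 4) with vehicle, a relative change of -12.7%. At the 12054 CpGs with 30 or more CpGs nearby it was 3.14% ± 0.0227 (SD, n = 3) against 3.64% ± 0.0695 (SD, n = 4), a relative change of -13.8%. This difference of -0.503 percentage points was no larger in size than that at mitochondrial CpGs, -0.640 percentage points. All 5 classes were lower in every 5aCdR library than in every vehicle library (exact permutation test, Benjamini-Hochberg adjusted p = 0.0286 in each).

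CpGs were also grouped by their level in the primary fetal cells, which took no part in this comparison. CpGs below 20% in primary cells went from 7.33% ± 0.107 (SD, n = 4) with vehicle to 6.18% ± 0.122 (SD, n = 3) after 5aCdR. CpGs between 20 and 80% went from 47.4% ± 0.155 (SD, n = 4) to 40.5% ± 0.218 (SD, n = 3). CpGs above 80% went from 79.3% ± 0.137 (SD, n = 4) to 70.5% ± 0.395 (SD, n = 3). The differences were -1.14, -6.89 and -8.83 percentage points (exact permutation test, p = 0.0286 in each of the 3 classes), and the relative changes were -15.6%, -14.5% and -11.1%. Within the lowest class, CpGs below 5% in primary cells differed by -0.607 percentage points, also no more in size than mitochondrial CpGs, and those between 5 and 20% by -3.43.

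**Figure D2:**
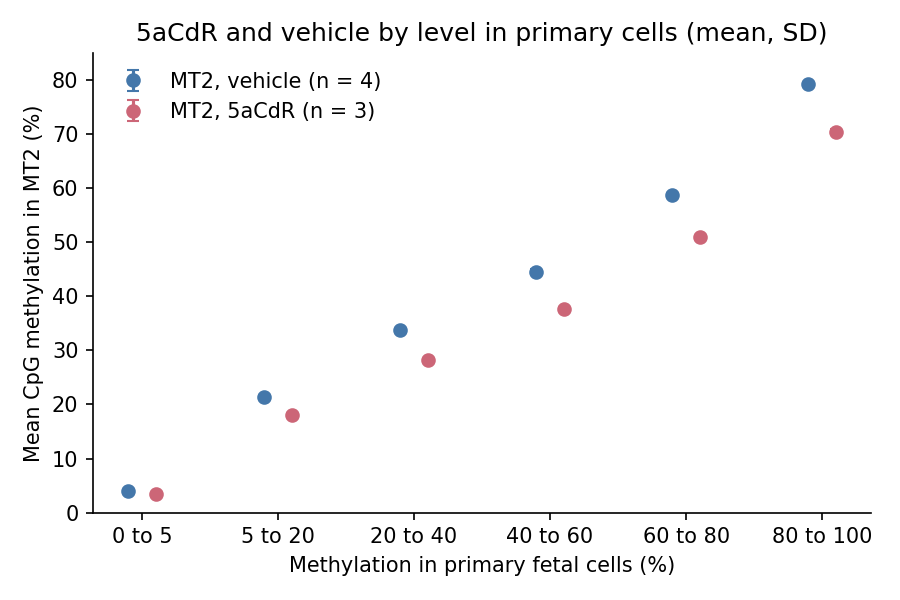
Mean CpG methylation in MT2 cells (percent, y axis) for CpGs grouped by their level in primary fetal cells (percent, x axis), with vehicle (blue, n = 4) and after 5aCdR (red, n = 3); points are means and bars SD between libraries. 5aCdR lay below vehicle in each of the 6 groups, from 3.44% against 4.04% in the lowest to 70.5% against 79.3% in the highest.

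Highly methylated CpGs became fewer and intermediate CpGs more frequent. The share of CpGs above 80% was 16.6% ± 0.265 (SD, n = 3) after 5aCdR and 26.1% ± 1.82 (SD, n = 4) with vehicle. The share between 20 and 80% was 33.0% ± 0.820 (SD, n = 3) against 24.2% ± 3.40 (SD, n = 4). Both differences had an exact permutation p = 0.0286 (Benjamini-Hochberg adjusted over the 3 classes, 0.0429). The share below 20% was 50.4% ± 0.576 (SD, n = 3) and 49.7% ± 1.58 (SD, n = 4), which did not pass the test (exact permutation, p = 0.429). The class shares moved with depth: the share between 20 and 80% was 27.5% and 26.8% in the deeper vehicle libraries and 21.7% and 20.9% in the shallower ones, and the 5aCdR libraries were deeper on average. At similar depth, the 5aCdR library of 36110136 reads had 16.9% of CpGs above 80% and 32.1% between 20 and 80%, and the vehicle library of 37595680 reads had 24.4% and 27.5%.

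Among regions, 149 of 18639 tiles of 1 kb passed an adjusted p of 0.05 in the quasi-binomial test, and 146 of them were lower after 5aCdR. Without tiles that hold a CpG of very high coverage, a limit added later, 65 of 18270 were called, 63 of them lower. Of the 146 lower tiles, 72 differed by at least 25 percentage points. The called tiles were highly methylated with vehicle: the median level of the 146 was 92.2% with vehicle and 61.5% after 5aCdR, while the median over all tested tiles with vehicle was 20.7%. They were also deeply covered, with a median of 473 reads per library, summed over the CpGs of a tile, against 197 for all tested tiles. The 10 tiles with the largest falls lay on 10 different scaffolds and fell by 44.7 to 58.5 percentage points. The tile at 1322001 to 1323000 of scaffold KB708307.1 was at 20.2% ± 4.24 (SD, n = 3) after 5aCdR and 78.7% ± 19.2 (SD, n = 4) with vehicle, from 3 CpGs and a median of 73 reads per library (quasi-binomial test, adjusted p = 0.0403). The tile at 786001 to 787000 of KB708302.1 was at 40.3% ± 11.6 (SD, n = 3) and 96.7% ± 5.74 (SD, n = 4), with a median of 151 reads (adjusted p = 0.0206, quasi-binomial test). On KB708200.1, the tile at 1777001 to 1778000 was fully methylated in all 4 vehicle libraries and was at 46.3% ± 11.3 (SD, n = 3) after 5aCdR. On KB708252.1, the tile at 4987001 to 4988000 went from 98.5% ± 3.03 (SD, n = 4) to 49.3% ± 5.77 (SD, n = 3), with the smallest adjusted p of the 10, 0.00556 in the quasi-binomial test. On KB708161.1, the tile at 9511001 to 9512000 was at 44.2% ± 1.33 (SD, n = 3) after 5aCdR and 90.6% ± 11.7 (SD, n = 4) with vehicle. A tile at 263001 to 264000 of KB708454.1 went from 88.9% ± 11.3 (SD, n = 4) to 38.2% ± 1.54 (SD, n = 3), and lay in a stretch whose share of reads was higher in MT2 than in primary cells.

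Only 3 tiles were higher after 5aCdR. The count of higher tiles was 1 with at least 20 reads, where fewer tiles were tested, and 1 with the replicate block. It was 0 without vehicle replicate 1, and 1 without 5aCdR replicate 1, 2 or 3 in turn. With the dispersion from all 3 groups or tiles of 500 bp it was 3. The simulation of this comparison gave 12 false calls among 18639 tiles, so the 3 are not shown to be true gains. The tile at 577001 to 578000 of KB708160.1 was at 85.4% ± 14.3 (SD, n = 3) after 5aCdR and 12.7% ± 10.6 (SD, n = 4) with vehicle (quasi-binomial test, adjusted p = 0.0211). The tile at 9001 to 10000 of APMT01211248.1 was at 40.8% ± 25.3 (SD, n = 3) and 0.413% ± 0.826 (SD, n = 4), with an adjusted p of 0.0297 in the same test. The tile at 2260001 to 2261000 of KB708244.1 was read as fully methylated in all 3 libraries after 5aCdR and was at 65.6% ± 23.0 (SD, n = 4) with vehicle, with 1 or more vehicle libraries also at 100%. It is named after its values were seen.

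In windows of 100 kb with at least 10 CpGs, a size added after the data were examined, 80.1% of the 5164 tested windows had a lower level after 5aCdR, with a median difference of -4.46 percentage points. The quasi-binomial test called 299 windows, of which 298 were lower. With the replicate number as a block it called 123, and 0 when the block fit used a prior of its own. The largest fall, from 80.3% ± 8.80 (SD, n = 4) to 48.8% ± 7.60 (SD, n = 3), was in the window at 1400001 to 1500000 of KB708288.1. The window at 4900001 to 5000000 of KB708253.1 went from 74.1% ± 4.08 (SD, n = 4) to 44.8% ± 10.9 (SD, n = 3). On KB708195.1, the window at 1200001 to 1300000 went from 42.6% ± 9.71 (SD, n = 4) to 14.4% ± 7.79 (SD, n = 3). The single window called higher, at 22400001 to 22500000 of KB708142.1, was at 20.3% ± 4.73 (SD, n = 3) after 5aCdR and 6.39% ± 3.18 (SD, n = 4) with vehicle (adjusted p = 0.0414, quasi-binomial test).

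At single CpGs, 132 of 155920 passed the adjusted threshold (13675 had an unadjusted p below 0.05), and 131 of them were lower. They had a median of 396 reads per library against 41 for all tested CpGs, and 6 were called once the CpGs of highest coverage were left out. On simulated libraries of the same depth, the test recovered 9% of CpGs and 95% of tiles of intermediate level changed by 50 percentage points in this comparison. The exception among the single CpGs, at position 480262 of KB708199.1, was read as unmethylated in all 4 vehicle libraries. It was at 99.2% ± 1.37 (SD, n = 3) after 5aCdR, from a median of 25 reads, and is named after its values were seen. The count of CpGs called higher was 0 with at least 20 reads, where fewer were tested, and 0 with the replicate block. It was also 0 without vehicle replicate 1 and without 5aCdR replicate 1, 2 or 3. Without vehicle replicate 2, 3 or 4 the count was 4, 2 or 1. The counts of this comparison depended on single libraries and on the model. Leaving out vehicle replicate 1, 2, 3 or 4 gave 48, 85, 75 or 41 tiles, and leaving out 5aCdR replicate 1, 2 or 3 gave 8, 9 or 8 CpGs, while edgeR's quasi-likelihood test called 2 tiles and limma on the mean logit 30. On simulated libraries edgeR recovered 0% of tiles changed by 50 percentage points in this comparison, and limma, run there on the logit of a tile's summed reads, also 0%. Leaving out vehicle replicate 1 or 4 gave 55 or 67 CpGs, and leaving out vehicle replicate 1 or 4 or 5aCdR replicate 2 gave 111, 178 or 183 windows. Of the 16 tiles and windows named by rule for this comparison, 5 were still called without vehicle replicate 1 and 5 without vehicle replicate 4, and between 7 and 10 without each of the other 5 libraries.

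**Figure D3:**
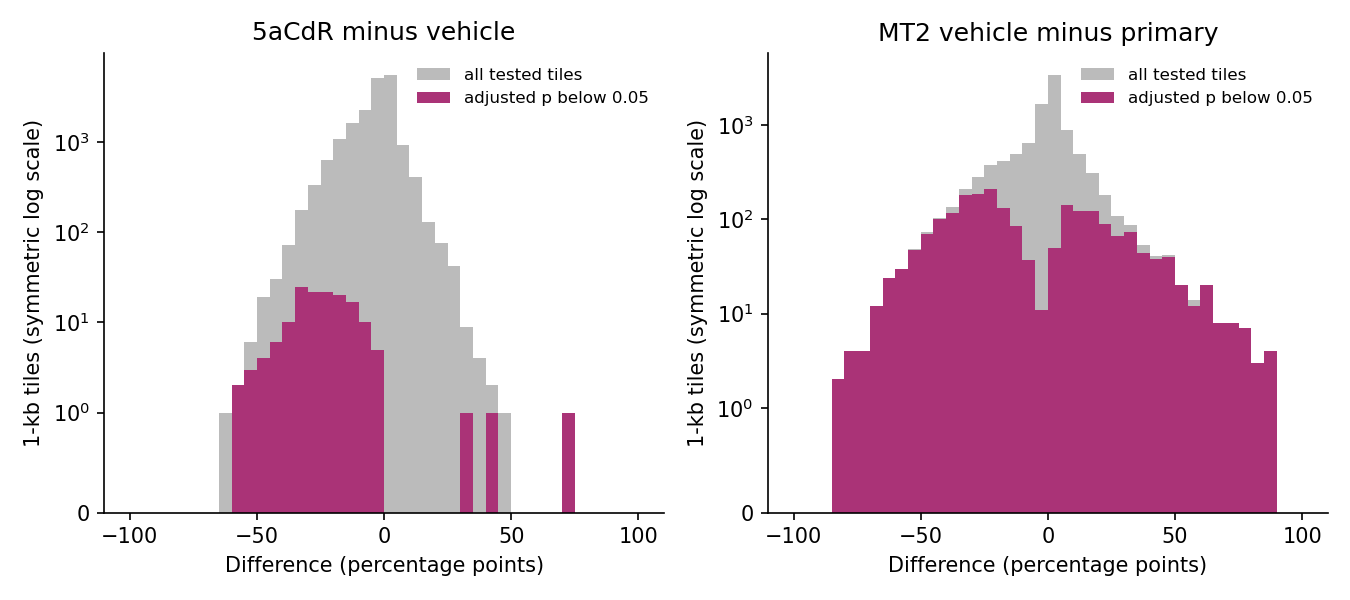
Number of 1-kb tiles (y axis, symmetric log scale) by the difference in methylation (percentage points, x axis, bars of 5 points) for 5aCdR minus vehicle (left) and MT2 vehicle minus primary (right). Grey bars are all tested tiles and purple bars those with an adjusted p below 0.05: 146 of the 149 called tiles lie below 0 on the left, and 1247 of 2117 on the right.

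The second comparison set MT2 cells with vehicle against the primary fetal cells. MT2 cells had less methylation than primary cells at sparse CpGs and more at dense CpGs, and regions differed in both directions. Mean CpG methylation was 38.1% ± 0.0700 (SD, n = 4) in MT2 and 41.1% ± 0.203 (SD, n = 4) in primary cells, a difference of -3.01 percentage points. Every MT2 library lay below every primary library (40.9% to 41.4%), and the exact two-sided permutation test gave p = 0.0286, the smallest that the 70 splits allow. With reads pooled over CpGs, which weights deeply read CpGs more, the difference was -6.15 percentage points, and over all CpGs that each library covered it was -1.003.

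The direction of the difference changed with local CpG density. The classes also differed in level, from 62.2% in primary cells at 1 to 4 CpGs nearby to 2.16% at 30 or more. Density was not tested among CpGs of equal level, so density and starting level are not separated here. At CpGs with 1 to 4 CpGs nearby, MT2 was at 53.8% ± 0.0483 (SD, n = 4) and primary cells at 62.2% ± 0.206 (SD, n = 4). At 5 to 9 CpGs nearby the levels were 52.9% ± 0.148 (SD, n = 4) and 56.7% ± 0.282 (SD, n = 4). At 10 to 19 they were 34.2% ± 0.126 (SD, n = 4) and 33.6% ± 0.353 (SD, n = 4), a difference that did not pass the test (exact permutation, adjusted p = 0.0571). At 20 to 29 CpGs nearby MT2 was higher, at 10.0% ± 0.0842 (SD, n = 4) against 7.75% ± 0.157 (SD, n = 4). At 30 or more, MT2 was at 3.64% ± 0.0695 (SD, n = 4) and primary cells at 2.16% ± 0.0661 (SD, n = 4), 1.68 times the primary level. The 4 classes other than 10 to 19 had an adjusted p of 0.0357 in the exact permutation test. With at least 20 reads per CpG, the difference at 10 to 19 CpGs nearby was -0.144 percentage points. Mitochondrial CpGs were called methylated in 3.08% of reads in MT2 and 4.37% ± 0.513 (SD, n = 4) in primary cells (exact permutation test, p = 0.0286), the opposite order to the dense CpGs.

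**Figure D4:**
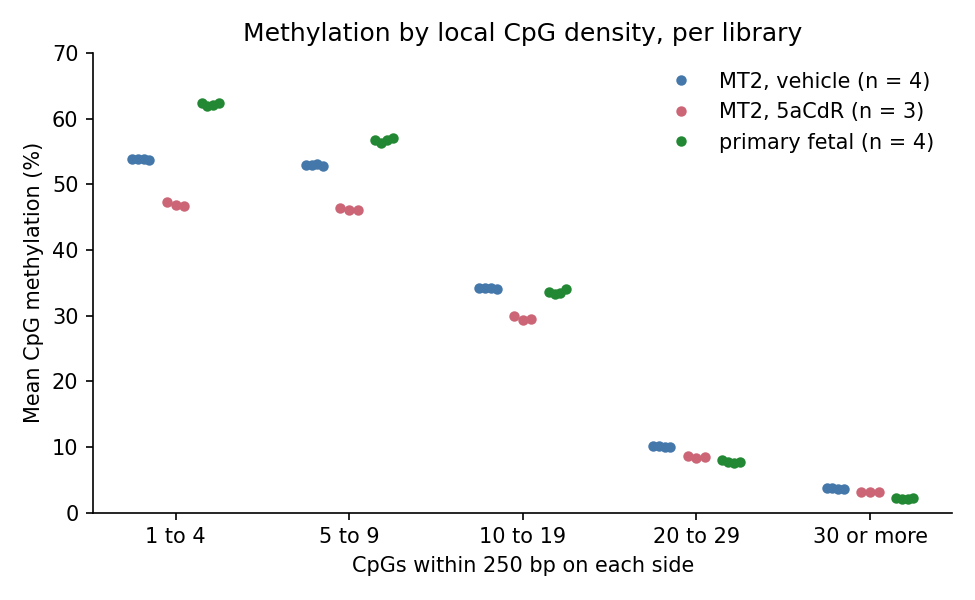
Mean CpG methylation (percent, y axis) of each library by the number of CpGs, among those covered in any library, within 250 bp on each side (x axis). Each point is 1 library. Primary cells lie above MT2 with vehicle at 1 to 4 CpGs nearby (62.2% against 53.8%) and below it at 30 or more (2.16% against 3.64%), and 5aCdR lies below vehicle in all 5 classes.

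The quasi-binomial test called 7802 of 91277 single CpGs, 5299 lower and 2503 higher in MT2. By at least 25 percentage points, 4886 were lower and 2196 higher. The count was 4870, 5109 and 4934 without vehicle replicate 1, vehicle replicate 4 and primary replicate 4. Among CpGs with 1 to 4 CpGs nearby, 11.5% were called lower and 3.34% higher in MT2. Among those with 30 or more nearby, 0.0488% were called lower and 0.627% higher. CpGs of that class were at 2.16% in primary cells and had little room to fall. The share of all CpGs below 20% was 49.7% ± 1.58 (SD, n = 4) in MT2 and 46.0% ± 1.39 (SD, n = 4) in primary cells, with an exact permutation p = 0.0286 that did not hold after adjustment over the 3 classes (0.0857). The shares between 20 and 80% (24.2% and 26.2%) and above 80% (26.1% and 27.8%) did not pass the test (exact permutation, p = 0.486 and p = 0.171). With at least 20 reads per CpG, a setting added later for this result, the share above 80% differed by -3.97 percentage points (exact permutation, p = 0.0286). With CpGs grouped by primary replicates 1 and 2 and compared with primary replicates 3 and 4, a grouping added later, MT2 differed by 2.79, -7.59 and -7.79 percentage points at CpGs below 20%, between 20 and 80% and above 80% (exact permutation p = 0.0667, the smallest that 15 splits allow).

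Of 10178 tiles of 1 kb, 2117 passed the test, 1247 lower and 870 higher in MT2. By at least 25 percentage points, 776 were lower and 343 higher. The lower tiles had a median level of 70.4% in primary cells and 32.9% in MT2. The higher tiles had a median level of 10.1% in primary cells and 49.7% in MT2. Among tiles with at least 5 CpGs, 512 were called and 45.1% of those were lower, against 58.9% of all called tiles. edgeR's quasi-likelihood test called 398 tiles, and on simulated libraries it recovered 25% of tiles changed by 50 percentage points in this comparison.

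The 10 tiles with the largest losses in MT2 lay on 10 scaffolds and had levels of 1.77% to 15.3% in MT2 and 73.3% to 90.5% in primary cells. The largest difference was at 1993001 to 1994000 of KB708228.1, with 2.57% ± 2.25 (SD, n = 4) in MT2 and 87.3% ± 4.87 (SD, n = 4) in primary cells, from 3 CpGs and a median of 186 reads per library (quasi-binomial test, adjusted p = 2.33e-06). The tile at 3270001 to 3271000 of KB708272.1 was at 2.95% ± 3.71 (SD, n = 4) and 83.6% ± 5.01 (SD, n = 4), with a median of 216 reads. On KB708166.1, the tile at 7950001 to 7951000 was at 1.77% ± 1.80 (SD, n = 4) in MT2 and 74.5% ± 3.16 (SD, n = 4) in primary cells. On KB708294.1, the tile at 3185001 to 3186000 was at 11.3% ± 7.14 (SD, n = 4) and 87.1% ± 9.53 (SD, n = 4). On KB708353.1, the tile at 453001 to 454000 was at 3.38% ± 2.61 (SD, n = 4) and 75.7% ± 15.8 (SD, n = 4), with a median of 256 reads.

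The 10 tiles with the largest gains lay on 10 scaffolds, at 82.1% or more in MT2 and at 14.5% or less in primary cells. The tile at 2732001 to 2733000 of KB708264.1 was fully methylated in all 4 MT2 libraries and was at 12.4% ± 10.6 (SD, n = 4) in primary cells, with a median of 162 reads (quasi-binomial test, adjusted p = 9.08e-06). The tile at 12091001 to 12092000 of KB708159.1 was at 97.8% ± 2.61 (SD, n = 4) and 12.1% ± 2.38 (SD, n = 4). The most deeply read of the 10, at 2229001 to 2230000 of KB708321.1 with a median of 886 reads, was at 94.8% ± 4.65 (SD, n = 4) in MT2 and 14.5% ± 4.07 (SD, n = 4) in primary cells, with an adjusted p of 2.00e-07 in the quasi-binomial test. On KB708183.1, the tile at 11775001 to 11776000 was at 86.0% ± 18.9 (SD, n = 4) in MT2 and 0.490% ± 0.980 (SD, n = 4) in primary cells. On KB708147.1, a scaffold with a higher share of reads in MT2 than in primary cells, the tile at 322001 to 323000 was at 92.3% ± 6.23 (SD, n = 4) and 12.5% ± 11.1 (SD, n = 4).

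Of 2767 windows of 100 kb, 530 were called, 311 lower and 219 higher in MT2. The largest loss was at 1300001 to 1400000 of KB708347.1, with 37.1% ± 6.01 (SD, n = 4) in MT2 and 80.8% ± 8.87 (SD, n = 4) in primary cells. On KB708214.1, the windows at 3300001 to 3400000 and at 1600001 to 1700000 were at 17.8% ± 3.34 and 10.3% ± 6.63 (SD, n = 4) in MT2, against 60.2% ± 9.09 and 51.2% ± 3.86 (SD, n = 4) in primary cells. The largest gain was at 3000001 to 3100000 of KB708226.1, with 74.2% ± 5.60 (SD, n = 4) in MT2 and 32.5% ± 9.19 (SD, n = 4) in primary cells. The window at 2400001 to 2500000 of KB708253.1 was at 86.2% ± 3.12 (SD, n = 4) and 46.1% ± 7.90 (SD, n = 4). The window at 4600001 to 4700000 of KB708239.1 was at 67.6% ± 5.53 (SD, n = 4) and 28.2% ± 12.5 (SD, n = 4). MT2 and primary cells differ in donor, cell mixture, passage and exposure at once, so the comparison does not separate these.

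The 5aCdR-treated MT2 cells were then set against the primary cells. In 20572 tiles, 3726 were called, 2666 lower and 1060 higher in the treated cells. Of the 2117 tiles that differed between vehicle-treated MT2 and primary cells, 1967 were also tested here and 1357 of them (69.0%) were called again, 1353 in the same direction. Both comparisons use the same 4 primary libraries. Independent lists would share 245 tiles in the same direction, a reference in which depth and level of the tiles were not matched. In 100 simulations of unchanged groups none was shared, but at most 3 tiles were called in a simulated comparison, so this 0 gives no reference. With the primary libraries split 2 and 2 between the comparisons, a check added later, 500 to 577 tiles were called in the same direction, where independent lists would share 56.7 to 70.7.

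Tiles called in both main comparisons were then counted. Among 9183 tiles tested in both, 111 were lower after 5aCdR. Of these, 33 were higher and 18 lower in MT2 than in primary cells, where independent lists would share 9.61 and 14.1. Tiles called after 5aCdR were highly methylated with vehicle and deeply covered. Level and depth were not matched, so an excess over independent lists does not by itself show a link. The comparisons share the vehicle libraries, and in 100 simulations of unchanged groups no tile was called in both. At most 2 tiles were called in either simulated comparison, so this 0 gives no reference for the overlap. With the 4 vehicle libraries split 2 and 2 between the comparisons, between 0 and 3 tiles were shared of the first kind, where independent lists would share 0.312 to 0.596, and between 2 and 4 of the second, where they would share 0.416 to 0.781. The covariance of the differences across tiles was -36.7 squared percentage points, against -19.9 on average in the simulations, and between -14.5 and -11.6 with the vehicle libraries split. The correlation across tiles, which are not independent replicates, was -0.252 against -0.503 in the simulations.

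Replicate libraries varied more than read counting alone would give. At common CpGs with a group mean between 20 and 80%, the median SD between libraries was 25.98 percentage points among vehicle wells, 18.6 among 5aCdR wells and 25.7 among fetuses. Binomial sampling of the reads would give 7.75, 5.86 and 7.67 percentage points. The variance was on average 15.2, 14.9 and 15.1 times the binomial one. No test between the groups was made. At single CpGs the correlation between libraries was 0.740 to 0.820 among vehicle wells, 0.748 to 0.799 among fetuses and 0.635 to 0.708 between vehicle wells and fetuses, each computed across CpGs within a pair of libraries.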

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

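The tests in this part were chosen after the data were examined; for the test of neighbouring CpGs and the count over other splits of the libraries for read share, the outcome had not been seen when its prediction was written.

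Read depth along the genome, which the comparisons of methylation do not use, differed between MT2 and primary cells. Of 199 scaffolds, 2 took a larger share of reads in MT2 with vehicle: KB708147.1 by 0.56 on the log2 scale (SE 0.028, limma, adjusted p = 4.18e-10), which is 1.48 times the primary share, and KB708184.1 by 0.42 (SE 0.027, limma, adjusted p = 9.04e-09). Both were also higher after 5aCdR, by 0.61 ± 0.012 and 0.45 ± 0.011 (SD, n = 3). On KB708184.1 all 11 windows of 500 kb from 6500001 to 12000000 were raised. Of the 13 windows before, 5 had enough CpGs for a value, the last of them ending at 3000000, and they lay between -0.24 and 0.19 with a median of -0.04, so the start of the rise is not resolved between 3000000 and 6500001. Among the 35 splits of the 8 vehicle and primary libraries 1, the real one, called as many as 2 scaffolds, and the highest of the others called 0. This argues against chance as a whole account, at the smallest share that 35 splits allow.

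For KB708147.1, 3 explanations were weighed. A different yield of CpG-dense or CpG-poor fragments is argued against, since the smallest difference among 4 classes of CpG density was 0.53, while on the other scaffolds the same classes moved by -0.06 to 0.06. A few positions of very high coverage are argued against, since all 36 of its 500-kb windows with enough CpGs for a value were raised, of 41 up to 20500000. An additional DNA copy in MT2, 3 in place of 2, would give 0.58 if every read were counted, and 0.56 was measured. The files list only positions with at least 10 reads, so the value that 3 copies would give in these sums is not known. The additional copy stays a hypothesis, since the ploidy of MT2 was not measured and donor and culture history differ together with the line.

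The mitochondrial sequence took 1.71 times as large a share of reads in vehicle-treated MT2 as in primary cells, 0.155% ± 0.0257 against 0.0907% ± 0.00891 (SD, n = 4 each, exact permutation test, p = 0.0286). The mean methylation of vehicle replicate 4, 38.0%, lay below the other 3 vehicle wells, which were all at 38.2%. It was the single library set apart among 48 groups of 4 values tested, where chance sets apart about 1 in 20.

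Methylation differences between MT2 and primary cells at single CpGs were weighed against 2 technical explanations. C-to-T variants between the line and the fetuses would change single CpGs. The nearest other tested CpG within 100 bp moved in the same direction by a median of 25.5 percentage points (5119 of 7802 called CpGs had such a neighbour). This argues against variants as the account of the calls as a set. The lower quartile was 5.77 percentage points, and 83.6% of the neighbours moved in the same direction. Variants at a part of the calls thus stay open, also at calls without a neighbour. Less complete bisulfite conversion in the primary libraries would raise their dense CpGs, and these were lower in primary cells: MT2 minus primary was 1.48 percentage points at CpGs with 30 or more CpGs nearby. Less complete conversion there thus cannot give this difference. Mitochondrial CpGs went the other way, at 4.37% in primary cells and 3.08% in MT2 (exact permutation test, p = 0.0286). A true gain at dense CpGs in MT2 could hide a conversion difference, so a part in the lower mean of MT2 stays open. Donor, cell mixture, passage and transformation stay open and were not tested apart.

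The spread between libraries, about 15 times the binomial variance, was weighed in the same way. Differences between wells as the whole account would make the dispersion grow in proportion to depth, but in the vehicle group it rose from 13.01 at 10 to 20 reads to 17.5 at 100 to 1000 reads, 1.34 times, which argues against that and is consistent with reads that are copies of few starting molecules. A smaller part from differences between wells stays open. Differences between the fetuses are argued against as a general account, since the dispersion of the primary group was 0.995 times that of the vehicle wells. At the 167 intermediate CpGs with over 1000 reads the primary group had a dispersion of 28.8, against 14.6 at 184 CpGs in the vehicle group, which also stays open.

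For each count of calls, 1 of 35 splits of the libraries, the real one, gave a count as large, a share of 0.0286 and the smallest that 35 splits allow. This argues against chance as the account of the counts but does not exclude it. The counts share libraries, wells of 1 line are not independent lines, and the criterion was written after the splits had been seen. The real counts of single CpGs were 132 (highest of the other splits, 34) for 5aCdR and 7802 (0) for MT2 against primary cells. For tiles they were 149 (0), 2117 (0) and, for 5aCdR-treated MT2 against primary cells, 3726 (4). For windows they were 299 (30) and 530 (0).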

How the results depend on the processing

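Chosen after the data were examined were all fits of windows and density classes, the 20-read minimum for class shares and for the SD between libraries, leaving out libraries for class shares, starting level and 5aCdR-treated MT2 against primary cells, leaving out the mitochondrial sequence, scaffolds of changed read share or tiles of very high coverage, the block fit's prior, and edgeR's dispersion trend. The other alternatives were fixed before.

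The lower mean methylation after 5aCdR and in MT2 kept its direction in all 25 alternatives run. Leaving out each library gave -5.03 to -4.80 percentage points for 5aCdR, with exact permutation p of 0.0667 to 0.1, the smallest that fewer libraries allow. Over the same fits, the change by starting level was -1.19 to -1.07, -7.01 to -6.82 and -9.06 to -8.71 percentage points, the share between 20 and 80% differed by 7.61 to 9.82 (exact permutation p up to 0.133) and the share above 80% by -10.03 to -8.87. For MT2 against primary cells the share below 20% differed by 3.03 to 4.21. With the class taken from vehicle replicates 1 and 2, the changes by starting level were -0.800, -6.83 and -10.7 (exact permutation p = 0.1, the smallest of 10 splits).

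At least 20 reads gave a difference of -3.97 percentage points in the share above 80% for MT2 against primary cells, now past the test, and reversed the difference at 10 to 19 CpGs nearby to -0.144 (exact permutation p = 0.6). The median SD between libraries was then 19.4 (vehicle), 14.2 (5aCdR) and 19.4 (primary) percentage points. It gave 258 CpGs and 78 windows for 5aCdR, 944 tiles and 99 windows for MT2 against primary cells, and 1578 tiles for 5aCdR-treated MT2 against primary cells; fewer units were tested. Without overdispersion the counts were 71101 CpGs, 11259 tiles and 4020 windows for 5aCdR, and 51868, 7177 and 2195 for MT2 against primary cells. The dispersion from all 3 groups gave 366 of 81297 CpGs and 180 of 2319 windows for 5aCdR. Fewer units were tested, as the third group also needed reads: the main fit called 132 of 155920 and 299 of 5164. At least 5 CpGs per tile gave 61 of 7331 and 512 of 3522 tiles. Leaving out the highest coverage gave 6 CpGs and 65 tiles for 5aCdR. edgeR called 2 and 398 tiles (3 and 388 in its first version, without a dispersion trend). limma on the mean logit called 30 for 5aCdR and 1579 for MT2 against primary cells. On simulated libraries edgeR recovered 0% of tiles changed by 50 points for 5aCdR and 25% for MT2 against primary cells. There limma, on the logit of summed reads, recovered 0% and 51%, and the quasi-binomial test 95% and 100%. The lower counts of edgeR and limma thus do not show that tiles were unchanged. The simulated tiles were drawn at the dispersion that the quasi-binomial test had fitted, which may favour that test. They do not show which of the counts is nearer the truth. With the vehicle libraries split 2 and 2, 3 to 7 tiles were called in both comparisons. Leaving out each library gave 8 to 110 CpGs, 41 to 124 tiles and 111 to 293 windows for 5aCdR, and 4870 to 6308 CpGs for MT2 against primary cells.

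Libraries with the same replicate number did not deviate together (correlations across CpGs of -0.0102 to 0.00381 and -0.00308 to 0.00270), and neither did those with other numbers (-0.0100 to 0.0167 and -0.00315 to 0.00312). The spread between libraries at single CpGs is large, so this check cannot exclude that the numbers pair them. With the replicate block, 21 CpGs, 65 tiles and 123 windows were called for 5aCdR, and 9351, 1966 and 493 for MT2 against primary cells. The first version of the block fit, with a prior of its own, called 0 CpGs, 0 tiles and 0 windows for 5aCdR (28510, 3298 and 961 at an unadjusted p below 0.05), and 13948, 1740 and 367 for MT2 against primary cells. On simulated libraries of the 5aCdR comparison, 13.1% of unchanged CpGs and 12.5% of unchanged tiles then had a p below 0.05, but 4.62% of windows, and 85% of windows changed by 50 points were recovered; the window counts thus depended on the prior. Under refits of the quasi-binomial test, 73 of 176 values of named regions for 5aCdR lost the call and kept the direction. For MT2 against primary cells all 322 values kept the call. edgeR, limma and the smaller tiles are not among these values, and the regions were chosen from the same libraries. At least 5 reads, promoters, gene lists and genomic context were not run. Power at single CpGs was low: a change of 50 percentage points was recovered at 9% of simulated CpGs for 5aCdR. The simulations did not vary depth.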

Other observations

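All tests in this part were chosen after the main results were seen.

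Differences between MT2 and primary cells ran together over neighbouring windows. Over 1006 pairs of adjacent 100-kb windows, the differences had a Pearson correlation of 0.205, and the largest size in 1000 shuffles of the windows was 0.110. In 49 of these pairs both windows were called, and 40 of them had the same direction, against 18.7 on average and at most 33 in the shuffles. Over 2584 pairs the changes after 5aCdR had a correlation of 0.0331, and the shuffles reached 0.0695. Both windows were called in 18 of these pairs, all in the same direction, against 8.64 on average and at most 19 in the shuffles (one-sided permutation p = 0.00500). As 298 of the 299 called windows were lower, the shared direction of these pairs carries no information of its own. Windows are not independent replicates and differ in depth, which was not matched, and the difference between the comparisons was not tested.

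On both scaffolds with a larger read share in MT2, methylation was higher in MT2 than in primary cells. On KB708147.1 methylation over 3020 CpGs was 35.3% ± 0.214 (SD, n = 4) in MT2 and 33.9% ± 0.518 (SD, n = 4) in primary cells, and on KB708184.1 over 1120 CpGs it was 24.1% ± 0.161 and 22.5% ± 0.545 (SD, n = 4). On the other scaffolds MT2 was lower, at 38.5% ± 0.0763 against 41.7% ± 0.188 (SD, n = 4). Each difference had an exact permutation p = 0.0286. The other scaffolds were pooled and CpG density was not matched, so these p-values do not show that the 2 scaffolds are unusual. After 5aCdR the level differed from vehicle by -4.72, -3.75 and -4.95 percentage points on KB708147.1, KB708184.1 and the other scaffolds. Smaller stretches also differed in read share: on scaffolds other than these 2, 15 windows of 500 kb were higher and 9 lower in MT2 with vehicle. In the 5aCdR-treated wells of the same line, 7 of the 15 and 1 of the 9 also passed an adjusted p of 0.05 against primary cells (limma), and 2 of the 24 had the opposite sign, so most of these windows are not shown to be traits of the line. KB708394.1 from 1 to 1000000 was higher by 0.60 and 0.71 on the log2 scale in its 2 windows, and KB708161.1 from 1000001 to 1500000 was at -0.79 (limma, adjusted p = 6.81e-05 in each). After 5aCdR these 3 windows were at 0.71, 0.65 and -0.64.

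The nearest other tested CpG within 100 bp of 85 CpGs called lower after 5aCdR fell by a median of 19.09 percentage points, and 94.1% of these neighbours were lower. Neighbours of 2244 uncalled CpGs, matched on the vehicle level of the CpG and of its neighbour and as far as possible on depth, had a median change of -9.34 percentage points and 81.6% were lower. In 1000 draws of 1 matched CpG for each called one, the median was -13.4 to -4.56 percentage points and the share lower 67.1% to 92.9%. The called CpGs were deeper, at a median of 488 reads against 240.5, and neighbours can lie on the same reads, so the excess does not show separate changes.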
